A study of Homo sapiens with 18 samples.

How the data were processed

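Total RNA of the cell lines H460, H2023 and ABC-1, taken after 24 h with CCS1477 or DMSO, was extracted with Sepasol, made into directional libraries with an MGI kit and sequenced in pairs of reads on a DNBSEQ instrument, per the labels. There were 18 libraries in 6 groups of 3. The aligner, the counting program, the use of strand in counting and the step that selected RNA from total RNA are not given in the sources used here. Each cell line has one deposited table, and its columns bear the same names in every table, so the line of each column was taken from the name of its table. The authors deposited log2 values, and the values themselves show how they were made: log2 of a whole number of reads divided by one scaling factor per library, plus a constant of 4, so that a row without reads stands at 2. All values of up to 1000 reads gave whole reads within 0.1 once this was undone, and each table had its own scaling. The design expected counts, or normalized values to which 1 would be added before the log, and the deposited constant of 4 was kept instead.

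The tables held 50485 rows for H460, 56303 for H2023 and 56523 for ABC-1, of which 16424, 18140 and 16910 were gene rows and the others transcript rows. Gene rows were analysed, and transcript rows, which held 9.19 to 10.7% of the reads of a library, were left out of the main fits. Coordinates and gene types came from GENCODE 29, on GRCh38, the build named in the submitters' notes. Symbols of some histone genes are newer than those of the tables. Recovered reads over all rows gave the depth and CPM of each library. At these depths a gene at 1 CPM had a counting error of 17.3 to 26.3% in 1 library. Intervals of ratios are exact (Clopper-Pearson) at 95%, and they cover counting error only, since reads without molecular identifiers are not independent molecules.

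In each line, genes with at least 1 CPM in at least 3 of the 6 libraries were tested on the deposited log2 values with limma-trend (limma 3.58.1 in R 4.3.3), 3 CCS1477 against 3 DMSO libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are log2 fold changes of CCS1477 over DMSO with the SE of the fit, and CPM are means with SD, computed over all recovered reads. Ratios of CPM can therefore differ from the log2 change. At low levels the gap is large, because the constant of 4 makes the log2 change smaller than that of the CPM. The difference between lines was tested in one limma fit over the 18 libraries, as the mean change of H460 and H2023 minus that of ABC-1, and each pair of lines was tested as well. Levels in untreated cells were set side by side as CPM, without a test. A test had been planned, but it was not run on the deposited values, since each table was normalized separately, nor on CPM. Overlaps between lines were compared with the number expected for independent lists. The comparisons, thresholds, 32 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

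Lists were tested with camera at a preset correlation of 0.01, with adjustment over all lists and lines, or over lists for the difference, and again with a correlation estimated for each list. Ranges of a list's adjusted p cover the alternatives tested with camera. Lists with fewer than 5 tested members were not tested. With the estimated correlation, each list call of a single line was lost, and in the difference only that of the G2/M list remained. Counts of list members that rose or fell are given over all genes tested and adjusted over the list alone.

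Genes were named by a fixed rule. NFE2L2, KEAP1, EP300, CREBBP and MYC were always named. In each line the 6 highest and 6 lowest log2 changes were taken among genes past the threshold with a mean of at least 5 CPM in the higher group and replicates that did not overlap, leaving out clone, antisense and small RNA names. Across lines the 8 genes that rose and the 8 that fell with the largest smallest change were taken. For the difference the 6 highest and 6 lowest values past the threshold in the mean and in both pairs of lines were taken. From each described list up to 4 members per fit with the smallest p could be named. Genes on the same or the opposite strand that overlap a named gene were looked up in the annotation. Some genes are not reported here.

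Alternatives were scaling by relative log expression or by library totals, limma-voom on recovered reads, no filter or 1 CPM in all libraries, and an absolute log2 change of at least 1. Others were one fit over the 18 libraries, the replicate number as a block, constants of 0.1 and 5 in place of 4, other set tests, single pairs of lines, and each library left out in turn. A constant of 1, scaling by the trimmed mean of M values, transcript rows added to their genes, a common CPM scale for the difference, and the overlap of lines without CCS1477 replicate 1 of H460 were chosen after seeing the data. Planned fits of count models were not run, because the design kept them for deposited counts and the deposited values are logs. The recovered reads could have been used for them. The labels do not say that replicate numbers pair the libraries.

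The fit was tested on simulated data in which every gene had the median dispersion measured between replicates of its line. In each line 50 genes were changed at each fold. Of genes with a 2-fold change, 98% were recovered in H460, 90% in H2023 and 94% in ABC-1, and of genes with a 1.25-fold change 56%, 60% and 68%. False calls made up 4.47%, 4.12% and 4.95% of calls, and 6.38% in the difference. The real data held many more changed genes, and a spread that can differ by gene and by library was not simulated. These rates therefore need not hold for the real fits. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.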

Results

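RNA sequencing profiled 3 human lung cancer cell lines after 24 h with CCS1477 or with its solvent DMSO. CCS1477, also called inobrodib, binds the bromodomain that the paralogous acetyltransferases p300 (EP300) and CBP (CREBBP) share, and both are coactivators that acetylate histones at enhancers and promoters. The series describes H460, a large cell carcinoma line, and H2023, labelled squamous, as NRF2-activated, and ABC-1, an adenocarcinoma line, as wildtype. NRF2, the product of NFE2L2, is the transcription factor of the antioxidant response, and KEAP1 is the adaptor that marks it for degradation. The sample descriptions give the dose as 5 µM and the series text as 5 mM, and it is taken here as 5 µM. Each line had 3 DMSO and 3 CCS1477 libraries, 18 in all. The labels do not say whether the 3 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Reads recovered per library ran from 26652278 to 33568192 in H460, from 15352622 to 18261167 in H2023 and from 14483979 to 17483291 in ABC-1. One library stood apart. In CCS1477 replicate 1 of H460, mitochondrial genes took 0.795% of reads, against 1.77 to 2.06% in the other 5 H460 libraries. Its squared difference from its replicates was 39.9 and 44.7 times the counting noise, against 2.90 to 7.01 times for every other pair of replicates.

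The lines differed in the level of NRF2 targets before treatment. Over the 19 genes of the glutathione, thioredoxin and iron list found in every table, the median in DMSO libraries was 799 CPM in H460, 684 CPM in H2023 and 84.3 CPM in ABC-1. In all, 18 of the 19 genes were higher in both H460 and H2023 than in ABC-1. For the list of drug metabolism and transport genes the medians were 229.6 CPM, 211 CPM and 9.36 CPM, and 13 of 16 genes were higher in both lines. The list of NADPH supply had medians of 294, 233 and 115 CPM, with 5 of 9 genes higher in both. These CPM came from recovered reads and do not use the scaling of the tables. The deposited values of the 3 tables were scaled separately, so the planned test between lines was not made. No test was made on CPM either, and the levels only stand side by side.

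NFE2L2 (ENSG00000116044, protein-coding, chromosome 2, 177227595 to 177392697 on GRCh38) fell in H2023 after CCS1477, from 156 ± 1.24 to 131 ± 8.91 CPM (mean ± SD, n = 3 in each group throughout), with a log2 fold change of -0.31 ± 0.05 (± SE throughout; adjusted p = 1.77e-04). It rose in ABC-1, from 98.5 ± 6.68 to 123 ± 2.12 CPM (0.26 ± 0.06, adjusted p = 0.00146). In H460 its log2 change of -0.08 ± 0.05 missed the threshold (adjusted p = 0.192). KEAP1 (ENSG00000079999, chromosome 19, 10486120 to 10503741) fell in H2023 (-0.32 ± 0.04, adjusted p = 4.53e-05) and in ABC-1 (-0.45 ± 0.05, adjusted p = 6.85e-06). Its log2 change in H460 was -0.20 ± 0.07 (adjusted p = 0.0454). EP300 (ENSG00000100393, chromosome 22, 41091786 to 41180079), a target of the compound, rose in H460 from 81.1 ± 1.20 to 104 ± 5.63 CPM (0.29 ± 0.05, adjusted p = 9.87e-04). Its log2 changes of 0.10 ± 0.05 in H2023 and -0.04 ± 0.03 in ABC-1 missed the threshold (adjusted p = 0.0740 and adjusted p = 0.311). CREBBP (ENSG00000005339, chromosome 16, 3725054 to 3880726) missed the threshold in each line, at 0.10 ± 0.06, -0.02 ± 0.04 and -0.10 ± 0.04 (adjusted p = 0.188, adjusted p = 0.676 and adjusted p = 0.0546). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), the growth regulator, fell in H460 (-0.29 ± 0.05, adjusted p = 9.65e-04) and H2023 (-0.31 ± 0.03, adjusted p = 1.64e-05), and its log2 change in ABC-1 was -0.16 ± 0.07 (adjusted p = 0.0459).

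The calls of KEAP1 in H460 and of MYC in ABC-1 depended on the setting. The first ended with scaling by library totals (log2 change -0.12, adjusted p = 0.180). It also ended with limma-voom (adjusted p = 0.0504), with no filter on low values (adjusted p = 0.0519), and without any of the libraries but CCS1477 replicate 1 (adjusted p = 0.0884 to 0.131). Over its alternatives the adjusted p ran from 8.22e-04 to 0.180. The call of MYC in ABC-1 ended with scaling by library totals (-0.11, adjusted p = 0.178), with no filter (adjusted p = 0.0533), and without DMSO replicate 2 or 3 or CCS1477 replicate 1 or 2 (adjusted p = 0.103, 0.132, 0.189 and 0.0674); its range was 0.00724 to 0.189.

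**Figure D1:**
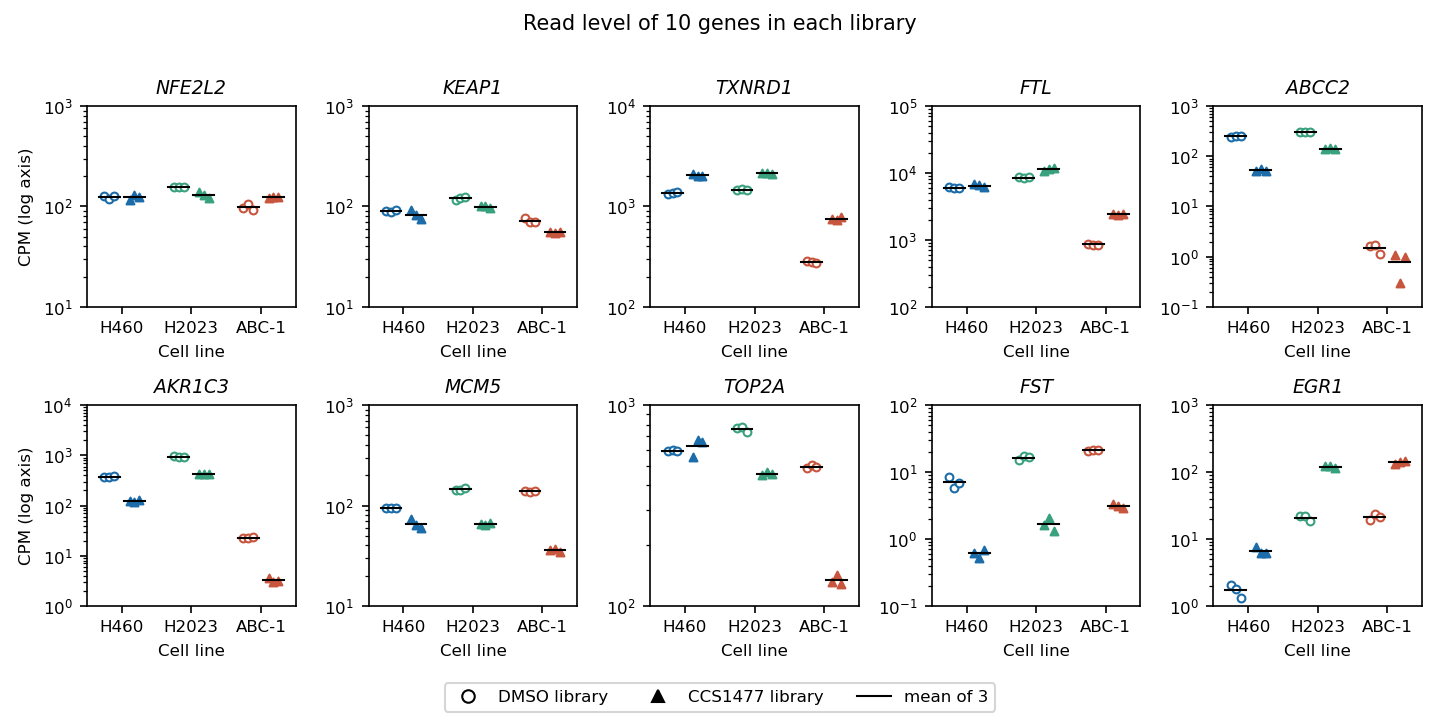
Level of 10 genes in each of the 18 libraries, in CPM on a log axis, by cell line and treatment, with a line at the mean of each group of 3. TXNRD1 and FTL rose in ABC-1 from lower levels than in H460 and H2023, while AKR1C3 and FST fell in all 3 lines.

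In H460, CCS1477 raised the motor genes KIF5C and KIF1A and lowered genes of the NF-kB list and NRF2 targets of drug metabolism. KIF5C and KIF1A, kinesin motors of axonal transport, rose from 0.106 ± 0.184 to 6.18 ± 1.60 CPM (4.90 ± 0.49, adjusted p = 8.17e-05) and from 1.07 ± 0.381 to 17.6 ± 2.25 CPM (3.84 ± 0.22, adjusted p = 4.80e-06). AMIGO3, a neuronal adhesion protein that overlaps GMPPB on its strand (4.62 ± 0.45), PCDH19, a protocadherin (3.41 ± 0.23), and CAPN5, a calpain protease (3.32 ± 0.26), rose as well, all with adjusted p between 1.10e-05 and 7.68e-05. The lowest log2 change belonged to SULT1A4, a sulfotransferase, which dropped from 9.87 ± 8.19 to 0.147 ± 0.0837 CPM (-4.96 ± 0.51, adjusted p = 9.62e-05), a value made uncertain by its near-identical copy SULT1A3 and an overlapping readthrough gene. DLGAP1, a scaffold of the postsynaptic density, fell from 5.05 ± 2.36 to 0.314 ± 0.152 CPM (-3.56 ± 0.36, adjusted p = 9.31e-05). In all, 7584 of 13516 tested genes passed an adjusted p of 0.05, 3811 higher and 3773 lower, and without CCS1477 replicate 1 there were 7594, with 3558 higher and 4036 lower. Scaling by library totals gave 60.2% higher calls in place of 50.3%. The replicates of the 2 groups did not overlap for 65.0% of tested genes in H460, 66.3% in H2023 and 71.8% in ABC-1, where chance gives 10%.

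The others of the 6 lowest log2 changes in H460 were those of structural RNAs. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 had log2 changes of -3.69 ± 1.10 (adjusted p = 0.0212) and -3.62 ± 1.13 (adjusted p = 0.0252), and RNA5-8SN2, a 5.8S ribosomal RNA gene with near-identical copies, -4.10 ± 1.16 (adjusted p = 0.0166). Without CCS1477 replicate 1 these were -2.16 for MT-RNR2 in H460, -2.06 for MT-RNR1 in H460 and -2.52 for RNA5-8SN2 in H460, all still past the threshold. Their calls ended, in turn, without DMSO replicate 1 or 2 (adjusted p = 0.0599 and 0.0571; range 1.34e-04 to 0.0599), without any 1 of the DMSO replicates (adjusted p = 0.0563 to 0.0680; range 2.73e-04 to 0.0680) and without DMSO replicate 1 (adjusted p = 0.0544; range 2.42e-04 to 0.0544). A second row for 7SK, the RNA that holds the elongation factor P-TEFb inactive, which overlaps the main 7SK gene on the same strand, changed by -4.63 ± 1.26 (adjusted p = 0.0139). The 13 tested members of the list of mitochondrially encoded RNAs had a median log2 change of -0.81 (adjusted p = 0.215), and of -0.12 without CCS1477 replicate 1. With a constant of 0.1 in place of 4 before the log, the log2 change was 8.57 for KIF5C in H460.

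The NRF2 targets of H460 split by function. Of 22 tested genes for drug metabolism and transport, 16 fell, with a median log2 change of -0.72 (adjusted p = 4.89e-06 by camera; adjusted p = 0.523 with an estimated correlation). ABCC2, an export pump for conjugates, fell from 249 ± 9.99 to 52.5 ± 2.91 CPM (-2.32 ± 0.05, adjusted p = 1.72e-07), and the aldo-keto reductases AKR1C2 and AKR1C3, which are close copies of each other, fell (-1.84 ± 0.05 and -1.71 ± 0.05). TRIM16, a ubiquitin ligase, also fell (-1.26 ± 0.04). Of 19 genes for glutathione, thioredoxin and iron, 9 rose and 5 fell (median 0.06, adjusted p = 0.375). Among them TXNRD1, thioredoxin reductase, rose from 1355 ± 28.0 to 2045 ± 69.9 CPM (0.52 ± 0.05, adjusted p = 5.20e-05), as did OSGIN1, a growth inhibitor induced by oxidative stress (0.93 ± 0.09), while MGST1, a glutathione transferase of membranes, changed by -0.70 ± 0.05 (adjusted p = 1.02e-05). Of 9 genes for NADPH supply, 3 rose and 4 fell (adjusted p = 0.675), among them RPIA of the pentose phosphate pathway (-0.61 ± 0.07) and IDH1 (-0.32 ± 0.04), both lower. With p-values adjusted over the list alone, the counts were the same for the first pair of lists and 4 higher and 4 lower for NADPH supply.

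Genes of the NF-kB, ATF4 and YAP/TEAD lists also fell in H460. In the list of NF-kB targets and cytokines, 12 of 17 genes fell and 3 rose (median -0.80, adjusted p = 8.09e-04; adjusted p = 0.712 with an estimated correlation). CXCL1, a chemokine for neutrophils, fell from 121 ± 2.24 to 18.1 ± 2.29 CPM (-2.82 ± 0.08, adjusted p = 2.70e-07), and so did TNFAIP3, a brake on NF-kB signalling (-1.67 ± 0.05). In one fit over all 18 libraries the test of the list NF-kB and inflammatory cytokines in H460 gave an adjusted p of 0.343 (range 2.06e-04 to 0.712 by camera). That fit held only genes found in every table, so it tested 11 members of the list. In the ATF4 list, 16 of 22 genes fell (median -0.46, adjusted p = 4.62e-04; adjusted p = 0.712 with an estimated correlation), including TRIB3, a pseudokinase induced by stress (-1.38 ± 0.06) and PSAT1 of serine synthesis (-0.46 ± 0.04). In the YAP/TEAD list, 12 of 18 fell (median -0.37, adjusted p = 0.00644; adjusted p = 0.712 with an estimated correlation), among them the coactivator WWTR1 (-0.74 ± 0.04), while CCN2, a matrix-associated growth factor, rose (0.90 ± 0.07). When adjusted over the list alone, these counts were the same but for 3 higher and 18 lower in the ATF4 list.

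Cell cycle genes fell little in H460. In the list of G1/S and DNA replication, 15 of 24 genes fell and 2 rose (median -0.24, adjusted p = 0.00295; adjusted p = 0.481 with an estimated correlation), including MCM5 of the replicative helicase (-0.61 ± 0.07, adjusted p = 1.29e-04) and its partner subunit MCM2 (-0.41 ± 0.04). In the list of G2/M and mitosis, 13 of 22 fell and 2 rose (median -0.16, adjusted p = 0.0392; adjusted p = 0.712 with an estimated correlation). The mitotic kinase AURKA was lower (-0.84 ± 0.05), and BUB1, a kinase of the spindle checkpoint, was higher (0.42 ± 0.04). The call of the list G2/M and mitosis in H460 ended without CCS1477 replicate 1 (adjusted p = 0.130) and with scaling by library totals (adjusted p = 0.0825), within a range of 0.010 to 0.712 by camera. In the MYC and ribosome biogenesis list, 11 of 24 fell (median -0.16, adjusted p = 0.0332; adjusted p = 0.582 with an estimated correlation), including the nucleolar protein NOLC1 (-0.36 ± 0.04). With scaling by library totals the list MYC and ribosome biogenesis in H460 had an adjusted p of 0.0847 (range 0.010 to 0.582 by camera). Adjusted over the list alone, the 3 counts were the same.

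**Figure D2:**
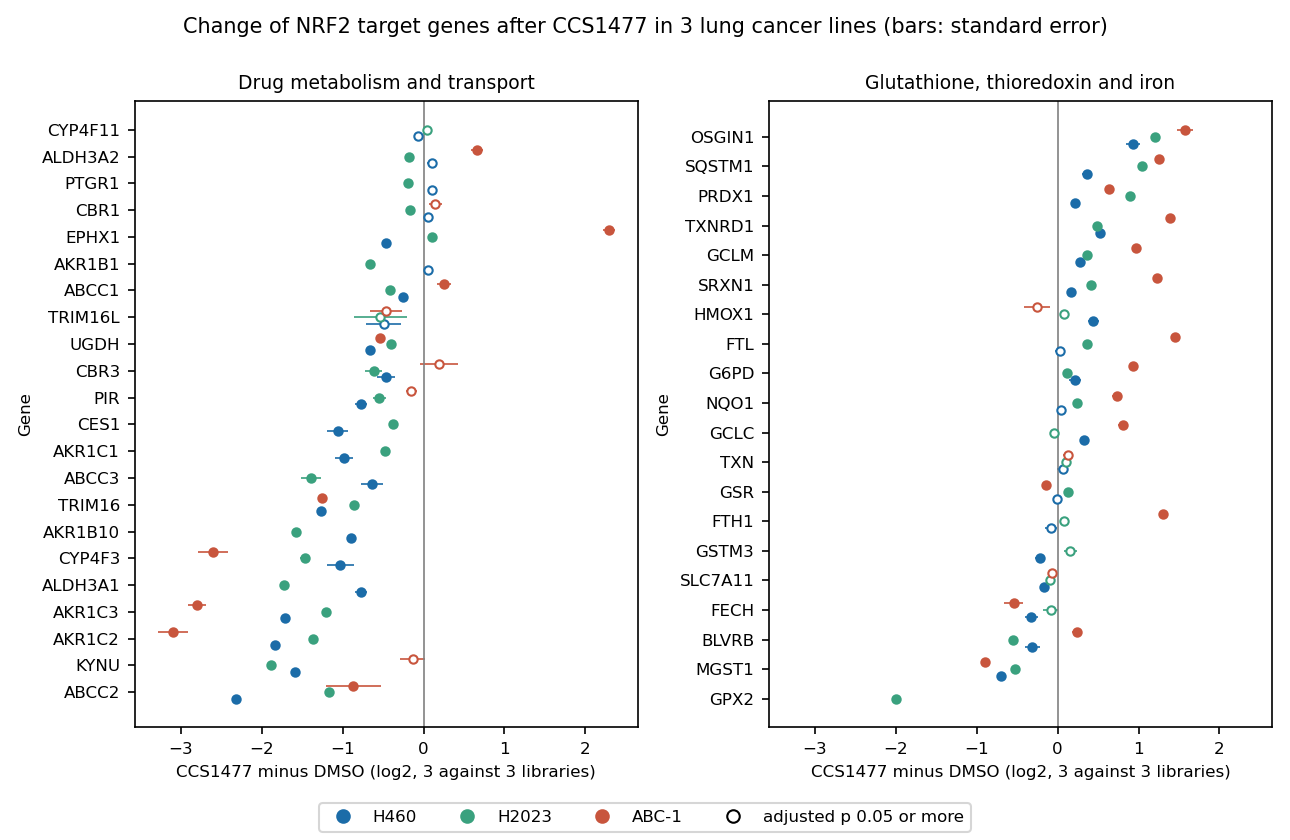
Log2 fold change of CCS1477 over DMSO ± SE for the members of the NRF2 lists of drug metabolism and transport and of glutathione, thioredoxin and iron in H460, H2023 and ABC-1, with open points where the adjusted p was 0.05 or more. Most drug metabolism members lay below 0 in H460 and H2023, and in the glutathione list FTL, FTH1, TXNRD1 and SRXN1 lay higher in ABC-1 than in the other lines.

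In H2023, CCS1477 raised NGFR and DPYSL3 and lowered genes of the epithelial and NF-kB lists. AMIGO3 rose from 0.0935 ± 0.162 to 6.99 ± 1.42 CPM (4.45 ± 0.32, adjusted p = 6.53e-07). NGFR, the p75 neurotrophin receptor, rose from 3 reads over the 3 DMSO libraries to 281 over the CCS1477 libraries, a CPM ratio of 100.2 with an exact 95% counting interval of 33.9 to 489 (adjusted p = 1.33e-07). DPYSL3 of neuronal growth cones (3.95 ± 0.23), BAIAP3 of vesicle exocytosis (3.64 ± 0.49), the connexin GJA3 (3.57 ± 0.27) and SCN3B, a sodium channel subunit (3.47 ± 0.44), rose too. AGR2, a disulfide isomerase of secretory epithelium, fell from 259.8 ± 9.48 to 27.8 ± 1.05 CPM (-3.27 ± 0.04, adjusted p = 5.70e-12), and FST, which binds activin, from 16.5 ± 1.19 to 1.66 ± 0.348 CPM (-3.19 ± 0.15, adjusted p = 3.24e-08). The lowest log2 changes were those of TM4SF20, a membrane protein of the tetraspanin-like family (-4.82 ± 0.17), TNS4, a tensin of focal adhesions (-3.98 ± 0.24), CASC19, a long noncoding RNA with a neighbour that overlaps on its strand (-3.79 ± 0.15), and CXCL1 (-3.73 ± 0.10). Past the threshold were 8824 of 14572 genes, 4170 higher and 4654 lower, and with scaling by library totals 4784 were higher and 4128 lower, so the larger share turned. With a constant of 0.1 the log2 changes grew to 8.24 for AMIGO3 in H2023 (6.69 with limma-voom), 7.24 for NGFR in H2023, 5.60 for BAIAP3 in H2023 and 5.64 for SCN3B in H2023.

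NRF2 targets of drug metabolism fell in H2023 as well. In their list 19 of 22 fell and 1 rose (median -0.58, adjusted p = 6.81e-08; adjusted p = 0.481 with an estimated correlation). KYNU, the kynureninase of tryptophan breakdown, fell from 205 ± 1.99 to 57.2 ± 0.651 CPM (-1.89 ± 0.03, adjusted p = 6.77e-11), AKR1B10, an aldo-keto reductase, from 3051 ± 52.4 to 1058 ± 19.2 CPM (-1.58 ± 0.03), as did the aldehyde dehydrogenase ALDH3A1 (-1.72 ± 0.04). In the glutathione, thioredoxin and iron list 10 of 20 rose and 3 fell (median 0.13, adjusted p = 0.0485; adjusted p = 0.712 with an estimated correlation). SQSTM1, the autophagy adaptor p62, rose from 1246 ± 16.7 to 2658 ± 42.7 CPM (1.04 ± 0.03), as did PRDX1, a peroxiredoxin (0.90 ± 0.04), whereas GPX2, a glutathione peroxidase of epithelia, fell from 168 ± 8.85 to 43.6 ± 1.37 CPM (-1.99 ± 0.05, adjusted p = 2.27e-10). The call of the list NRF2 targets: glutathione, thioredoxin and iron in H2023 ended with 1 CPM required in all libraries (adjusted p = 0.0577) and with transcript rows added to their genes (adjusted p = 0.0560). It ended as well without DMSO replicate 1, 2 or 3 or CCS1477 replicate 2 (adjusted p = 0.0659, 0.0573, 0.0797 and 0.0594), over a range of 0.0184 to 0.712 by camera. In the NADPH list 4 of 9 rose and 3 fell (adjusted p = 0.802), with TKT, transketolase, lower (-0.26 ± 0.03). With p-values adjusted over the list alone, the 3 counts were the same.

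Genes of the epithelial, NF-kB, histone and chaperone lists fell in H2023 too. Of 14 epithelial and lung lineage genes 12 fell (median -0.98, adjusted p = 6.57e-05; adjusted p = 0.481 with an estimated correlation). CDH1, the epithelial cadherin, fell from 47.4 ± 3.97 to 8.11 ± 0.589 CPM (-2.56 ± 0.09, adjusted p = 2.40e-09), and so did the keratin KRT19 (-1.33 ± 0.05). In one fit over all 18 libraries the list epithelial and lung lineage in H2023 had an adjusted p of 0.0559 (range 1.21e-05 to 0.481 by camera). That fit held only genes found in every table, so it tested 8 members, without CDH1. In the NF-kB list 15 of 17 fell (median -1.43, adjusted p = 1.53e-06; adjusted p = 0.481 with an estimated correlation). The chemokine CXCL5 fell from 423 ± 17.8 to 62.5 ± 2.22 CPM (-2.81 ± 0.04, adjusted p = 2.27e-11), as did BIRC3, an inhibitor of apoptosis (-1.43 ± 0.05). All 13 tested replication-dependent histone genes fell (median -1.25, adjusted p = 3.81e-08; adjusted p = 0.582 with an estimated correlation), such as H3C2 (-1.54 ± 0.05) and the linker histone H1-2 (-1.30 ± 0.05). In the list of ER chaperones and heat shock 11 of 18 fell (median -0.18, adjusted p = 0.0251; adjusted p = 0.712 with an estimated correlation), including XBP1, a factor of the unfolded protein response (-1.33 ± 0.05). When adjusted over the list alone, these counts were the same.

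Genes of DNA replication, mitosis and ribosome biogenesis were also lower in H2023. In the G1/S list 20 of 24 fell (median -0.64, adjusted p = 7.77e-08; adjusted p = 0.582 with an estimated correlation). MCM5 fell from 146 ± 3.75 to 65.3 ± 1.64 CPM and GINS1 of the replication fork fell too (-1.19 ± 0.05). In the G2/M list 19 of 22 fell (median -0.49, adjusted p = 1.28e-07; adjusted p = 0.523 with an estimated correlation). UBE2C, a ubiquitin carrier of mitotic exit, fell (-1.18 ± 0.04), as did TOP2A, the topoisomerase of proliferating cells, from 762 ± 24.4 to 454 ± 7.47 CPM (-0.80 ± 0.04). In the MYC list 19 of 24 fell (median -0.32, adjusted p = 4.40e-04; adjusted p = 0.582 with an estimated correlation), including NOP2, a methyltransferase of ribosomal RNA (-0.43 ± 0.03). In the YAP/TEAD list 13 of 18 fell and 4 rose (median -0.40, adjusted p = 0.0485; adjusted p = 0.849 with an estimated correlation): NT5E, an ectonucleotidase, fell (-1.46 ± 0.05) as did the receptor kinase AXL (-0.85 ± 0.04), while CCN2 rose (2.15 ± 0.07). The call of the list YAP/TEAD targets in H2023 ended with 1 CPM required in all libraries (adjusted p = 0.0659) and without CCS1477 replicate 2 or 3 (adjusted p = 0.0680 and 0.0796; range 0.0245 to 0.849 by camera). Adjusted over the list alone, the 4 counts were the same.

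In ABC-1, CCS1477 lowered genes of the G1/S and G2/M lists and raised genes of the immediate-early, NF-kB and glutathione lists. The keratin KRT4 fell from 231 ± 14.8 to 5.30 ± 0.252 CPM (-5.44 ± 0.06, adjusted p = 5.59e-13), the keratin KRT13 from 83.3 ± 1.12 to 2.47 ± 0.260 CPM (-5.00 ± 0.09), and GABRP, the pi subunit of the GABA-A receptor, from 66.9 ± 1.67 to 0.992 ± 0.0996 CPM (-5.80 ± 0.11). The homeobox gene MEOX1 dropped from 343 reads over the DMSO libraries to 1 read over the CCS1477 libraries, a DMSO over CCS1477 ratio of 377 with an exact 95% counting interval of 67.2 to 14919.7 (adjusted p = 4.42e-09). The connexin GJA5 (-4.57 ± 0.22) and BCO1, which cleaves beta-carotene (-4.42 ± 0.25), fell too. TUBA1A, the alpha tubulin of neurons, rose from 13.4 ± 0.928 to 159.5 ± 5.91 CPM (3.49 ± 0.06, adjusted p = 1.05e-11), and TPPP, which promotes tubulin polymerization, from 3.08 ± 0.634 to 38.9 ± 1.24 CPM (3.52 ± 0.13). HBA1, a haemoglobin alpha gene with a near-identical copy (4.87 ± 0.31), CCDC88A, which binds actin (4.48 ± 0.29) and BAIAP3 (3.44 ± 0.33) were among the other strongest increases. Of 13543 genes 8949 passed the threshold, 4535 higher and 4414 lower, or 5183 and 4005 with scaling by library totals. With a constant of 0.1 the log2 changes were 6.88 for CCDC88A in ABC-1 and -9.11 for MEOX1 in ABC-1 (-7.51 with limma-voom), and with transcript rows added to their genes 2.83 for CCDC88A in ABC-1.

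Every tested gene of the G2/M list fell in ABC-1, 22 of 22 (median -1.68, adjusted p = 1.17e-13; adjusted p = 0.481 with an estimated correlation). TOP2A fell from 493 ± 7.74 to 134 ± 7.48 CPM (-1.94 ± 0.04, adjusted p = 4.56e-11), the proliferation marker MKI67 from 573 ± 13.9 to 187 ± 6.63 CPM (-1.67 ± 0.04), as did the kinetochore protein CENPF (-1.88 ± 0.03). In the G1/S list 23 of 24 fell (median -1.28, adjusted p = 6.15e-10; adjusted p = 0.582 with an estimated correlation). MCM5 fell from 139 ± 1.72 to 35.9 ± 1.25 CPM, as did RRM1 of nucleotide reduction (-1.31 ± 0.04). All 13 histone genes fell (median -1.44, adjusted p = 3.81e-08; adjusted p = 0.582 with an estimated correlation), including H3C2 (-1.97 ± 0.05). In the MYC list 19 of 24 fell (median -0.39, adjusted p = 2.57e-04; adjusted p = 0.582 with an estimated correlation), including CDK4 (-0.94 ± 0.05), and ODC1, the first enzyme of polyamine synthesis, rose (0.85 ± 0.04). In the ribosomal protein list 18 of 24 fell (median -0.26, adjusted p = 0.00118; adjusted p = 0.742 with an estimated correlation), such as RPL18 (-0.32 ± 0.04). In the ATF4 list 14 of 20 fell (median -0.53, adjusted p = 0.00207; adjusted p = 0.712 with an estimated correlation). CTH, which makes cysteine, fell from 65.3 ± 1.63 to 20.7 ± 0.650 CPM (-1.70 ± 0.06), and so did ATF4 itself (-0.85 ± 0.03). With p-values adjusted over the list alone, these counts were the same.

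Genes of antioxidant defence, inflammation and immediate-early signalling rose in ABC-1. In the glutathione, thioredoxin and iron list 12 of 18 rose and 3 fell (median 0.77, adjusted p = 0.00118; adjusted p = 0.730 with an estimated correlation). The ferritin chains FTL and FTH1 rose from 854 ± 25.8 to 2422 ± 71.6 CPM (1.44 ± 0.04, adjusted p = 1.43e-10) and from 339 ± 5.39 to 875 ± 54.6 CPM (1.31 ± 0.05), and TXNRD1 from 277 ± 7.37 to 757 ± 22.8 CPM (1.39 ± 0.04). In the drug metabolism list 3 of 14 rose and 6 fell (adjusted p = 0.367), with EPHX1, the microsomal epoxide hydrolase, up from 8.11 ± 0.455 to 42.4 ± 2.00 CPM (2.29 ± 0.07) and AKR1C3 down (-2.80 ± 0.11). In the NADPH list 4 of 9 rose and 3 fell (adjusted p = 0.907), with TALDO1, a transaldolase, at -0.56 ± 0.04 (adjusted p = 2.90e-07). In the immediate-early and AP-1 list 19 of 23 rose (median 1.58, adjusted p = 5.82e-06; adjusted p = 0.582 with an estimated correlation). EGR1 rose from 21.5 ± 1.89 to 139 ± 7.75 CPM (2.62 ± 0.07), as did the AP-1 subunit JUND (1.98 ± 0.06). In the NF-kB list 8 of 9 rose (median 0.72, adjusted p = 0.00838; adjusted p = 0.481 with an estimated correlation), including the subunit RELB (1.96 ± 0.12) and PTGS2, the inducible cyclooxygenase (1.22 ± 0.09). In the cholesterol list 13 of 21 rose (median 0.26, adjusted p = 0.0386; adjusted p = 0.849 with an estimated correlation). INSIG1, a sterol-regulated membrane protein of the endoplasmic reticulum, rose from 74.5 ± 0.793 to 207 ± 8.20 CPM (1.41 ± 0.04). When adjusted over the list alone, these counts were the same but for 3 higher and 7 lower in the drug metabolism list.

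Genes that changed the same way in all 3 lines numbered 1731 higher and 1495 lower of 11757 tested in each, against 373.9 and 316.1 for independent lists of the same sizes, and the lines share no libraries. Without CCS1477 replicate 1 of H460 there were 1664 genes changed the same way in all 3 lines (higher) and 1600 genes changed the same way in all 3 lines (lower). Among the increases with the largest smallest change were TPPP (2.75 ± 0.18, 2.50 ± 0.14 and 3.52 ± 0.13 in H460, H2023 and ABC-1), the ubiquitin ligase TRIM36 (2.06, 2.70 and 2.87), GJA3 (1.96, 3.57 and 3.39), TMOD2, a neuronal tropomodulin (2.36, 1.96 and 2.10) and NATD1 (1.92, 2.42 and 1.92). The immediate-early factor EGR1 rose by log2 changes of 1.81, 2.47 and 2.62, and DCXR, which reduces L-xylulose and overlaps a neighbour on its strand, by 1.76, 2.03 and 1.71 (1.14 for DCXR in H460 with transcript rows added). All of these had adjusted p between 1.74e-10 and 8.81e-05 in every line.

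Among the shared decreases FST fell, with log2 changes of -3.33 ± 0.19, -3.19 ± 0.15 and -2.70 ± 0.10, and so did KCNN4, a potassium channel opened by calcium, with -2.61, -2.82 and -4.22 (-6.43 for KCNN4 in ABC-1 with a constant of 0.1), and the keratin KRT80, with -2.87, -2.59 and -2.63. The tensin TNS3 (-1.52, -1.80 and -1.92), the formin FMNL1 (-1.41, -1.49 and -2.24), the histone gene H2BC14, named HIST1H2BM in the tables (-1.57, -1.79 and -2.37) and E2F2, a factor of S phase entry (-1.51, -1.72 and -2.68), fell as well. So did AKR1C2 (-1.84, -1.37 and -3.10). Across genes, which are not independent replicates, the fold changes of H460 and H2023 had a Pearson r of 0.617, those of H460 and ABC-1 0.453 and those of H2023 and ABC-1 0.565, and 418, 934 and 789 genes passed the threshold with opposite signs.

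**Figure D3:**
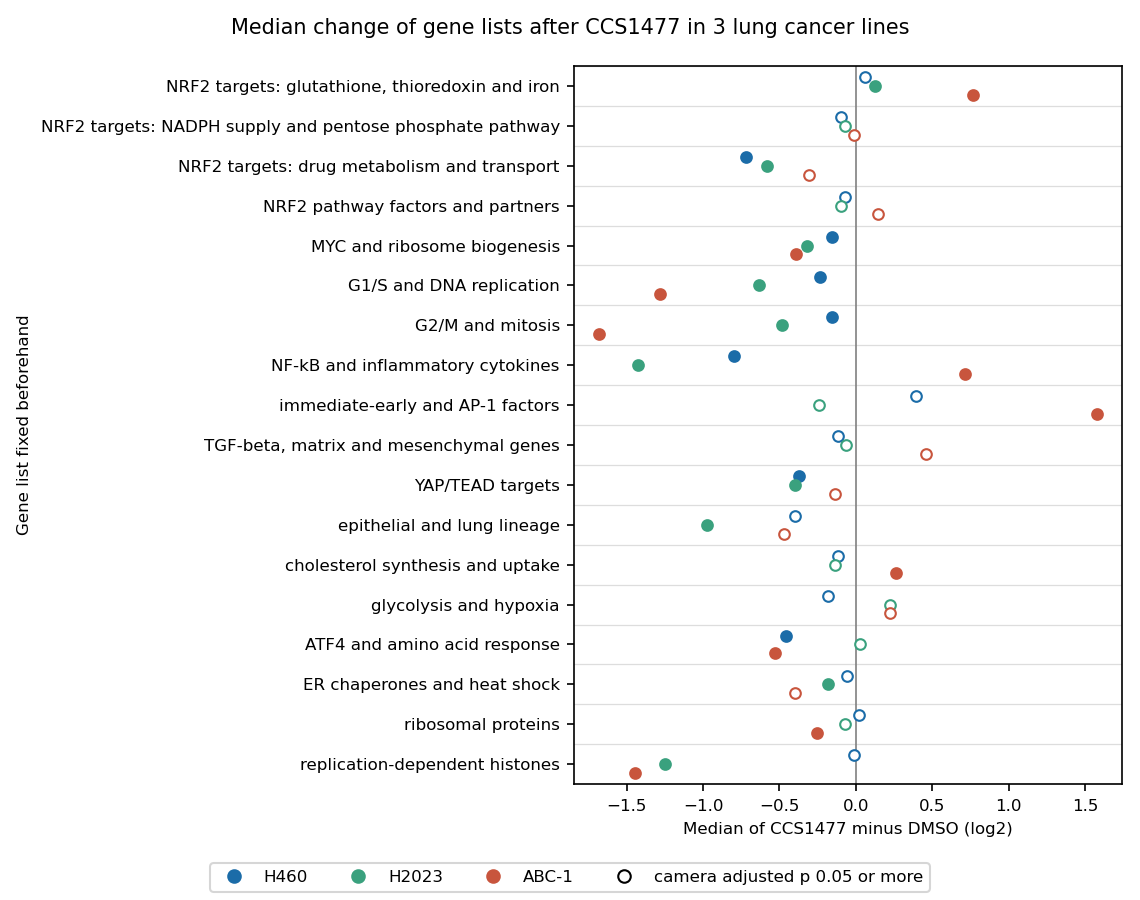
Median log2 fold change of CCS1477 over DMSO for 18 gene lists in H460, H2023 and ABC-1, with open points where the adjusted p of camera with a preset correlation was 0.05 or more. The G2/M list lay lowest in ABC-1, at -1.68, and each median covers the genes tested in its line.

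The comparison the series sets up, NRF2-activated lines against ABC-1, was tested as the mean of the H460 and H2023 log2 fold changes minus that of ABC-1. With 1 wildtype line, NRF2 state and cell line cannot be told apart. Mitotic genes fell further in ABC-1. All 22 tested genes of the G2/M list had a positive difference past the threshold (median 1.36, adjusted p = 4.83e-22; adjusted p = 0.0219 with an estimated correlation), the only list called with both correlations. For BUB1 the difference was 1.95 ± 0.06 (adjusted p = 5.98e-14), for PLK1, a mitotic kinase, 1.34 ± 0.05 and for TPX2, a spindle assembly factor, 1.33 ± 0.05. NRF2 targets of the glutathione, thioredoxin and iron list had the higher change in ABC-1 (median difference -0.55, adjusted p = 4.41e-04, and adjusted p = 0.262 with an estimated correlation). Past the threshold, 11 of 19 differences lay below 0 and 5 above. FTL had a difference of -1.25 ± 0.06 (adjusted p = 7.87e-12), FTH1 -1.31 ± 0.07 and SRXN1, sulfiredoxin, -0.95 ± 0.05. For drug metabolism the median difference was -0.55, and the list missed the threshold (adjusted p = 0.0849). Of its 16 genes, 10 lay below 0 and 4 above, past the threshold for single genes. KYNU (-1.60 ± 0.10) and EPHX1 (-2.47 ± 0.05) lay below 0 and AKR1C3 (1.34 ± 0.07) above. The test of the list NRF2 targets: drug metabolism and transport difference passed with 1 CPM required in all libraries (adjusted p = 0.0450) and without ABC-1 CCS1477 replicate 2 or 3 (adjusted p = 0.0494 and 0.0467), over a range of 0.0450 to 0.310 by camera. The NADPH list had 4 higher and 3 lower of 9 (adjusted p = 0.842), among them ME1, malic enzyme (2.19 ± 0.10).

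In the difference, 6291 of 13647 genes passed the threshold, 3144 with the higher change in the NRF2-activated lines and 3147 with the higher change in ABC-1. H460 alone against ABC-1 gave 6299, H2023 alone 5554, and H460 against H2023 3697; without CCS1477 replicate 1 of H460 the mean contrast gave 6453. Among the regulators, NFE2L2 (-0.46 ± 0.07, adjusted p = 2.78e-05) had the lower and EP300 (0.23 ± 0.05, adjusted p = 8.99e-04) the higher change in the NRF2-activated lines. KEAP1 had a difference of 0.19 ± 0.07 (adjusted p = 0.0333), and those of MYC (-0.14 ± 0.06, adjusted p = 0.0736) and CREBBP (0.13 ± 0.06, adjusted p = 0.0823) missed the threshold. The call of KEAP1 difference ended with limma-voom (adjusted p = 0.0592), with H2023 alone against ABC-1 (adjusted p = 0.222) and without 1 library in 6 cases (adjusted p = 0.0528 to 0.105; range 0.00516 to 0.222), and that of EP300 difference with H2023 alone (0.14, adjusted p = 0.0628; range 1.58e-04 to 0.0628).

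Most tested genes of the NF-kB, immediate-early and YAP/TEAD lists had the higher change in ABC-1. The median difference was -1.48 for the NF-kB list, with 8 of 11 genes below 0 and past the threshold (adjusted p = 2.84e-05, and adjusted p = 0.0881 with an estimated correlation). Over these 11 genes the medians were -0.31 in H460, -0.58 in H2023 and 0.69 in ABC-1, where chemokine genes such as CXCL1 and CXCL5 were not among those tested. The median difference was -0.71 for the immediate-early and AP-1 list, with 15 of 21 below 0 and past the threshold (adjusted p = 3.80e-07, and adjusted p = 0.0881 with an estimated correlation). For TGF-beta and matrix genes it was -0.99, with 8 of 17 below 0 and past the threshold (adjusted p = 0.00462, and adjusted p = 0.105 with an estimated correlation). For YAP/TEAD targets it was -0.45, with 12 of 18 below 0 and past the threshold (adjusted p = 3.13e-05, and adjusted p = 0.183 with an estimated correlation). TNFAIP3 (-1.95 ± 0.11), PTGS2 (-2.68 ± 0.21), the ERK phosphatase DUSP6 (-2.30 ± 0.12), IER3 (-2.15 ± 0.07), TGFB1 (-1.52 ± 0.08), the urokinase receptor PLAUR (-1.90 ± 0.09) and CCN1 (-1.79 ± 0.07) had the higher change in ABC-1, each past the threshold. The cholesterol list had 15 of 20 differences below 0 and past the threshold (median -0.42, adjusted p = 3.80e-07, and adjusted p = 0.183 with an estimated correlation). Among them MSMO1 had -1.03 ± 0.05 and IDI1 -1.01 ± 0.06. The glycolysis and hypoxia list had 12 of 20 below 0 and past the threshold (median -0.27, adjusted p = 0.00462, and adjusted p = 0.262 with an estimated correlation). Over these 20 genes the median log2 changes were -0.16 in H460, 0.22 in H2023 and 0.22 in ABC-1. At the median, H2023 thus did not stand apart from ABC-1. BNIP3 of mitophagy had a difference of -1.50 ± 0.08. The call of the list TGF-beta, matrix and mesenchymal genes difference ended with 1 CPM required in all libraries (adjusted p = 0.221; range 0.00245 to 0.221 by camera). Adjusted over the list alone, the counts were the same but for 10 below 0 in the NF-kB list; those of the NRF2 lists and of G2/M were the same too.

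The G1/S, histone, ribosomal protein, MYC and ATF4 lists had the lower change in ABC-1. The G1/S list had 22 of 24 differences above 0 and past the threshold (median 0.75, adjusted p = 7.56e-12, and adjusted p = 0.0881 with an estimated correlation). TYMS of thymidylate synthesis had 1.34 ± 0.05 and MCM5 1.09 ± 0.06. The histone list had 11 of 13 above 0 and past the threshold (median 0.77, adjusted p = 1.70e-06, and adjusted p = 0.183 with an estimated correlation). The ribosomal protein list had 15 of 24 above 0 and past the threshold (median 0.21, adjusted p = 6.91e-04, and adjusted p = 0.483 with an estimated correlation). The MYC list had 13 of 24 above 0 and past the threshold (median 0.23, adjusted p = 0.0303, and adjusted p = 0.353 with an estimated correlation), with CDK4 at 0.65 ± 0.05. The ATF4 list had 9 of 21 above 0 and past the threshold (median 0.19, adjusted p = 0.0101, and adjusted p = 0.415 with an estimated correlation), with CTH at 1.82 ± 0.09. The list of NRF2 pathway factors and partners had 8 of 14 below 0 and past the threshold (median -0.31, adjusted p = 0.0362, and adjusted p = 0.310 with an estimated correlation). Among them were the NRF2 partner MAFK (-0.92 ± 0.09) and the kinase GSK3B (-0.58 ± 0.07). With H2023 alone against ABC-1, calls ended for the list replication-dependent histones difference (adjusted p = 0.179; range 7.12e-10 to 0.183 by camera) and the list MYC and ribosome biogenesis difference (adjusted p = 0.182; range 0.00975 to 0.353 by camera). So did that of the list NRF2 pathway factors and partners difference (adjusted p = 0.110, with 0.0878 for 1 CPM required in all libraries and 0.0554 without ABC-1 DMSO replicate 3; range 0.0220 to 0.310 by camera). With H460 alone the call ended for the list ATF4 and amino acid response difference (adjusted p = 0.838; range 9.24e-06 to 0.838 by camera). With p-values adjusted over the list alone, the counts above 0 were 14 for MYC, 19 for ribosomal proteins and 10 for ATF4, and the other counts were the same.

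The highest differences between the lines were those of AMIGO3 (4.66 ± 0.99), KCNH2, the potassium channel hERG (3.58 ± 0.37), the protease-like gene PRSS35 (3.49 ± 0.18), MALAT1, a nuclear noncoding RNA (3.48 ± 0.99), VWA5B2 (3.46 ± 0.30) and the basal keratin KRT15 (3.29 ± 0.40). KCNH2 in ABC-1 fell from 18.0 ± 0.908 to 4.41 ± 1.33 CPM, PRSS35 from 426 ± 8.29 to 114 ± 1.46 CPM. The lowest were SULT1A4 (-5.93 ± 1.36), CCDC88A (-4.76 ± 0.25), EIF3CL, a near copy of the initiation factor gene EIF3C (-3.70 ± 1.16), HBA1 (-3.16 ± 0.35), TGFB2, a TGF-beta ligand (-3.13 ± 0.16), and SNHG5, a host of small nucleolar RNAs that overlaps 1 of them (-2.99 ± 0.72). TGFB2 fell in H460 from 49.3 ± 6.50 to 7.90 ± 0.296 CPM and in H2023 from 25.4 ± 1.69 to 4.44 ± 0.252 CPM. In their own fits KCNH2 and KRT15 were below the filter on low values in H460 and H2023, TGFB2 in ABC-1, VWA5B2 in H460, HBA1 in H2023 and SULT1A4 in H2023 and ABC-1. Their differences rest on low levels there, such as log2 changes of 1.80 and 1.24 for KCNH2 in H460 and H2023 and 0.53 for TGFB2 in ABC-1. With transcript rows added to their genes the log2 change turned from -0.63 to 0.32 for MALAT1 in H2023 and from -3.78 to 0.74 for MALAT1 in ABC-1, and without ABC-1 CCS1477 replicate 1 the value of MALAT1 difference was 2.07. The call of EIF3CL difference ended without ABC-1 DMSO replicate 2 or 3 (adjusted p = 0.060 and 0.0592) and was -5.61 without replicate 1, with a range of 7.01e-12 to 0.060. With a constant of 0.1 the calls of HBA1 difference (-3.55, adjusted p = 0.0674, range 2.37e-07 to 0.0674) and KRT15 difference (1.72, adjusted p = 0.197, range 1.99e-07 to 0.197) ended, the latter being 1.81 with H2023 alone. Others grew to 7.60 for AMIGO3 difference, 6.18 for VWA5B2 difference, -10.71 for SULT1A4 difference and -7.15 for CCDC88A difference, and to -7.22 for EIF3CL difference and -6.52 for SNHG5 difference. Reads of SULT1A4, EIF3CL and HBA1 can be split with near-identical copies, and it is not given whether counting used the strand, so values of genes that overlap others are uncertain. Like AMIGO3 and the others so marked, CAPN5, DLGAP1, KEAP1, NFE2L2, RNA5-8SN2, TGFB2, TMOD2 and TRIM36 overlap another gene on their strand. So do EIF3CL, EP300, KRT15, MALAT1, NGFR and VWA5B2. Overlaps on the opposite strand matter as well if counting ignored the strand. Among others, TUBA1A overlaps TUBA1C, TPPP overlaps CEP72 and BAIAP3 overlaps TSR3 in this way.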

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

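The tests of a scaling shift, of NRF2 activation and of NRF2 state as the whole cause, the matched checks on GC content and length, and the median position of the library that stood apart were chosen only after the result was seen. Results are listed here because the difference in response between the NRF2-activated lines and ABC-1 passed its test, or because they came from rows that the comparisons did not use. As medians over lists, the differences (mean of H460 and H2023 minus ABC-1) were -0.55 for glutathione, thioredoxin and iron, -0.31 for NRF2 pathway factors, 0.23 for MYC and ribosome biogenesis, 0.75 for G1/S, 1.36 for G2/M, -1.48 for NF-kB, -0.71 for immediate-early and AP-1 factors and -0.99 for TGF-beta and matrix genes. They were -0.45 for YAP/TEAD targets, -0.42 for cholesterol, -0.27 for glycolysis and hypoxia, 0.19 for ATF4, 0.21 for ribosomal proteins and 0.77 for histones. A mean of H460 and H2023 can hide a gap between them. Median log2 changes in H460, H2023 and ABC-1 were -0.16, 0.22 and 0.22 for glycolysis and hypoxia. For histones they were -0.01, -1.25 and -1.44. Among regulators the differences were -0.46 ± 0.07 for NFE2L2, 0.19 ± 0.07 for KEAP1 and 0.23 ± 0.05 for EP300. The highest were 4.66 for AMIGO3, 3.58 for KCNH2, 3.49 for PRSS35, 3.48 for MALAT1, 3.46 for VWA5B2 and 3.29 for KRT15. The lowest were -5.93 for SULT1A4, -4.76 for CCDC88A, -3.70 for EIF3CL, -3.16 for HBA1, -3.13 for TGFB2 and -2.99 for SNHG5. Transcript rows, which the comparisons did not use, passed the threshold for 556 of 13733 rows in H460 (192 higher), 429 of 13860 in H2023 (177 higher) and 1082 of 15510 in ABC-1 (446 higher).

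Other splits of the libraries tested whether the counts of genes past the threshold can arise by chance. Within a line, 3 against 3 libraries make 10 splits, too few for a share under 0.05: the real split called 7584 genes in H460, 8824 in H2023 and 8949 in ABC-1, and the highest of the others 0, 0 and 1. For the difference, 2 of 100 splits drawn within the lines called as many genes as the real 6291, and the highest other called 6477. Of these splits 72 mixed treated and DMSO libraries in every line and called at most 2 genes, while all 11 others that kept the groups of ABC-1 apart called 1000 or more. The count thus followed from which groups were mixed, so whether chance can be excluded for the difference stays undecided. For genes changed the same way in all 3 lines, 1 of 100 splits, the real one, reached 3226, and the highest other called 0. Mixed splits of a line called at most 1 gene, so a split that mixed any line could share almost none. This outcome thus followed from the single lines, and whether chance can be excluded stays undecided here too.

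NRF2 targets of drug metabolism fell in H460 and H2023 while the list of glutathione, thioredoxin and iron did not. Reads shared between near-identical genes were argued against, since without such genes the medians were still -0.55 in H460 and -0.48 in H2023, with 9 and 11 of 12 genes lower, although in ABC-1 the median turned from -0.31 to 0.15, with 3 higher and 2 lower of 9. A scaling shift of the treated libraries, which moves both lists alike, does not account for the gap between the lists. The difference between them changed by -0.86 ± 0.019 in H460 and -0.89 ± 0.040 in H2023, at least 22.6 standard errors from 0. This gap is the pattern itself, so its size does not tell a fall of one list from a rise of the other. The lists lay apart in ABC-1 too, with medians of -0.31 for drug metabolism and 0.77 for glutathione, thioredoxin and iron. Such a gap was thus not particular to the NRF2-activated lines. In ABC-1 the drug metabolism list missed its test (adjusted p = 0.367 by camera). NRF2 activation of the line may take part. However, the difference of the drug metabolism list against ABC-1 had an adjusted p of 0.0849, and ABC-1 expressed fewer genes of the list. NRF2 state and cell line therefore cannot be told apart.

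Cell cycle genes fell further in ABC-1 than in the NRF2-activated lines. Depth and the constant added before the log were argued against, because the G2/M list kept 100.5% of its median difference on recovered reads with precision weights. The difference did not rest on CCS1477 replicate 1 of H460 either, with 100.6% kept without it, although 1 library carries little weight in this mean. H460 and H2023, both called NRF2-activated, differed by a median of 0.41 (adjusted p = 8.62e-07), less than the 1.15 between H2023 and ABC-1, which does not decide on NRF2 state as the whole cause. What stays open is a difference between the lines in growth, sensitivity to CCS1477 or NRF2 state, which may each contribute and which cannot be told apart with 1 wildtype line.

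CCS1477 replicate 1 of H460 held fewer mitochondrial reads than the other H460 libraries and differed most from its replicates. GC content went with its deviation from its replicates across nuclear genes (Spearman rho 0.567; genes are not independent replicates), which met the bound set in advance for this cause. However, 4230 nuclear genes in the GC range of mitochondrial genes deviated by -0.035, 1.56% of the mitochondrial -2.26, so GC content did not account for the mitochondrial reads, although it may account for other deviations. For transcript length rho was -0.176, between the bounds set in advance, and 1687 nuclear genes in the mitochondrial length range deviated by 0.087, opposite in sign. Of the 7594 genes called without it, 87.3% lay on the treated side, under the bound of 90% set in advance against a mislabelled DMSO library. For 934 of them the other CCS1477 libraries differed from DMSO by an absolute log2 change of at least 1. Over these the median position was 1.01 of the way from DMSO to the other CCS1477 libraries, where a DMSO library would lie near 0. The cause of the lower mitochondrial share stays open, and no biological explanation was tested.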

How the results depend on the processing

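Constants of 1, scaling by the trimmed mean of M values, transcript rows added to their genes, the common CPM scale and the overlap without 1 library were chosen only after the result was seen. Of list results under an alternative, 2590 kept their side of the threshold, 58 newly passed it and 61 no longer did. Direction was compared only for results past the threshold in the main fits. For named genes these were 15904, 163 and 241, and 13 results past the threshold in the main fits turned direction. Of counts of genes, 315 stayed within 1.5 times the main count and 12 did not, all 12 with an absolute log2 change of at least 1, a rule that by construction calls fewer genes.

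That rule gave 1095 genes changed by CCS1477 in H460 (545 higher, 550 lower), 1387 genes changed by CCS1477 in H2023 (635 and 752), 1932 genes changed by CCS1477 in ABC-1 (820 and 1112) and 148 genes changed the same way in all 3 lines (101 and 47). With single libraries left out there were 6376 to 7594 in H460, 7930 to 8092 in H2023, 8219 to 8560 in ABC-1, 2879 to 3264 in all 3 lines and 5856 to 6453 in the difference in response between the NRF2-activated lines and ABC-1. With the replicate number as a block there were 7356, 8806, 8768, 3103 and 6119. The block ended the calls of KEAP1 in H460 (adjusted p = 0.0624) and KEAP1 difference (adjusted p = 0.0501), whose alternatives ranged from 8.22e-04 to 0.180 and from 0.00516 to 0.222, and of RPS3 in H460, HSP90AA1 in ABC-1, RPLP1 in ABC-1, NT5E difference, ESRP1 difference and RPL4 difference (adjusted p = 0.0516 to 0.130). The libraries share only a number. As a hint from the data, each DMSO library of H2023 correlated best with the CCS1477 library of its own number. Of the DMSO libraries, 2 of 3 did so in H460 and 0 of 3 in ABC-1. The hint is weak, since these correlations were only 0.034 to 0.044 in H2023.

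As adjusted p, an estimated correlation ended calls with 0.523 for the list NRF2 targets: drug metabolism and transport in H460, 0.481 for the list NRF2 targets: drug metabolism and transport in H2023 and 0.712 for the list NRF2 targets: glutathione, thioredoxin and iron in H2023. They were 0.730 for the list NRF2 targets: glutathione, thioredoxin and iron in ABC-1 and 0.262 for the list NRF2 targets: glutathione, thioredoxin and iron difference. The set test fry, which asks only whether a list moves and not whether it moves more than other genes, passed with 0.0466 for the list NRF2 targets: glutathione, thioredoxin and iron in H460 and 0.00915 for the list NRF2 targets: NADPH supply and pentose phosphate pathway in H2023. It also passed with 6.44e-04 for the list NRF2 targets: drug metabolism and transport in ABC-1 and 5.85e-07 for the list NRF2 targets: drug metabolism and transport difference. The glutathione list in H2023 gave 0.0577 with 1 CPM in all libraries, 0.0560 with transcript rows added and 0.0184 to 0.0797 with single libraries left out, and the drug metabolism difference 0.0450 and 0.0467 to 0.152; the cause was not tested.

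Among results past the threshold in the main fits, direction turned, with transcript rows added, for MALAT1 in H2023 (0.32) and MALAT1 in ABC-1 (0.74). With H460 alone against ABC-1 it turned for TRIM16 difference (-0.0049), NT5E difference (0.42) and KRT19 difference (0.48). With H2023 alone it turned for KIF1A difference (-0.97), NOTCH3 difference (0.0010), NOLC1 difference (-0.0072), FOSL2 difference (-0.36), AJUBA difference (0.039), PDIA4 difference (-0.026), H2BC12 difference (-0.026) and H1-2 difference (-0.20). A single pair leaves out 1 line by construction, and the cause was otherwise not tested. Planned count-model fits and the planned test of the untreated difference were not run. Depth limits genes near 1 CPM, where the counting error was 17.3 to 26.3% in 1 library.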

Other observations

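The test of REST targets was chosen only after the result that prompted it, the increase of single genes known from neurons, was seen. The rule that would exclude NRF2 state as the whole cause was rewritten after its own value was seen, because a gap between 2 activated lines did not bear on it, and under the new rule the value decides nothing. Several fixed lists missed the threshold in a line although members passed it. Of interferon-stimulated genes 4 rose and 10 fell of 21 in H460 (median -0.44, adjusted p = 0.238), 8 rose and 7 fell of 21 in H2023 (median 0.12, adjusted p = 0.882) and 5 rose and 10 fell of 17 in ABC-1 (median -0.53, adjusted p = 0.394). Of p53 targets and CDK inhibitors 7 rose and 1 fell of 18 in H460 (median 0.13, adjusted p = 0.155), 12 rose and 7 fell of 19 in H2023 (median 0.33, adjusted p = 0.204) and 8 rose and 7 fell of 19 in ABC-1 (median -0.08, adjusted p = 0.856). Of fatty acid genes 8 rose and 5 fell of 20 in H460 (median 0.08, adjusted p = 0.731), 6 rose and 8 fell of 20 in H2023 (median -0.06, adjusted p = 0.969) and 11 rose and 4 fell of 16 in ABC-1 (median 0.30, adjusted p = 0.0950). Of lysosome and autophagy genes 6 rose and 4 fell of 17 in H460 (median 0.11, adjusted p = 0.510), 10 rose and 4 fell of 17 in H2023 (median 0.13, adjusted p = 0.0761) and 8 rose and 3 fell of 18 in ABC-1 (median 0.06, adjusted p = 0.383). Of neuroendocrine markers 3 rose and 1 fell of 7 in H460 (median 0.21, adjusted p = 0.383) and 6 rose and 1 fell of 8 in H2023 (median 0.41, adjusted p = 0.118). Adjusted over the list alone, these counts were the same but for 12 higher in the lysosome list and 9 lower in the fatty acid list, both in H2023.

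In lists that missed the threshold, median and mean, in this order, differed in sign for antigen presentation in H460 (0.19 and -0.06). In H2023 they did for interferon-stimulated genes (0.12 and -0.25), immediate-early and AP-1 factors (-0.24 and 0.08), fatty acid genes (-0.06 and 0.06) and the ATF4 list (0.03 and -0.03). In ABC-1 they did for acetyltransferases and bromodomain factors (-0.02 and 0.01), p53 targets (-0.08 and 0.25), YAP/TEAD targets (-0.14 and 0.37), metallothioneins (0.11 and -0.11), receptor tyrosine kinases (-0.26 and 0.20) and immune checkpoint genes (-0.20 and 0.16). The test pointed against both median and mean for receptor tyrosine kinases in H460 (0.03 and 0.12) and NADPH supply in ABC-1 (-0.01 and -0.22), and against the median for the lysosome list in the difference (0.07). The stromal and blood cell lists, and the neuroendocrine list in ABC-1, had fewer than 5 tested members and were not tested.

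The noncoding RNAs 7SL, 7SK and RPPH1 together took 8.36 ± 0.562% of reads in DMSO and 6.51 ± 0.967% in CCS1477 libraries of H460 (SD, n = 3), 5.63 ± 0.657% and 7.30 ± 0.456% in H2023, and 3.58 ± 0.0724% and 4.03 ± 0.274% in ABC-1. In ABC-1, DMSO replicate 3 held 2.40% mitochondrial reads against 1.58 to 1.69% in the other DMSO libraries.

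Genes enriched in a line may lose expression when the coactivators of its enhancers are inhibited. Among genes at least 4 times higher in DMSO replicate 1 of a line than in the others, the median log2 change, computed from DMSO replicates 2 and 3, differed from that of other genes by -0.56 in H460 (166 genes), -0.49 in H2023 (208) and -0.50 in ABC-1 (478), -0.49 being the smallest of them. Level rather than enrichment was argued against, since 90.8%, 105.0% and 96.4% of the difference was kept among genes of matched level. In retained-intron rows the median log2 change minus that of their gene was 0.068 in H460, 0.116 in H2023 and 0.066 in ABC-1 (3601, 3645 and 4792 rows), between the bounds set in advance, so a shift of retained introns stays open at 0.066. 

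KIF1A in H460, NGFR in H2023 and TUBA1A in ABC-1, which rose, are known from neurons, while DLGAP1, also known from them, fell in H460. These were picked by eye, with no fixed list behind them. Loss of repression by REST, the repressor of neuronal genes, may be a source. Of the list of REST targets 10 rose and 3 fell of 15 in H460, 12 and 4 of 17 in H2023 and 12 and 2 of 15 in ABC-1, with medians of 1.20, 0.82 and 1.65. Camera gave an unadjusted p of 0.00585, 0.0142 and 1.53e-04, and 0.263, 0.115 and 0.0155 with an estimated correlation. A gene was tested only with at least 1 CPM in at least 3 of the 6 libraries. Members silent in DMSO libraries were therefore counted only where they rose, and silent members that did not rise were left out. This can push the counts, medians and p-values toward a rise, so they do not give the share of REST targets that rose. REST mRNA had log2 changes of 0.19 ± 0.04 in H460 (adjusted p = 0.00391), 0.08 in H2023 (adjusted p = 0.156) and 0.21 in ABC-1 (adjusted p = 8.23e-04), so it was lower in 0 lines by limma. This argues against a fall of REST mRNA, and leaves its protein and its activity open.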
